A study of Mus musculus with 9 samples.

How the data were processed

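Tumour cells were sorted from lungs into 3 groups of 3 libraries (mCherryLow, mCherryHigh and DTC). Per the labels' protocols, RNA was extracted with the RNAqueous-Micro kit, full-length cDNA was made with a SMART-seq kit and libraries with Nextera XT. Per the submitters' processing notes, reads were mapped to mm9. The aligner and the counting tool are not given in the sources used here. The deposited table holds CPM (read counts scaled to a common library total) for 24012 genes in 9 columns, as the authors labelled it, and 0 columns were left unmatched to a sample.

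In each column the smallest step between values was 1 read divided by the library total. All values were whole multiples of it within 0.01 read, with a largest deviation of 0.000265 read, so whole reads and library totals were recovered. Totals ran from 643748 to 11861200 reads. A count of 0 allows up to 3 reads, which is 4.66 CPM in mCherryHigh 1, the shallowest library, and 0.253 CPM in mCherryLow 6, the deepest. Symbols shared by 648 entries of the table were kept apart by gene ID.

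The groups, the comparisons (mCherryHigh with mCherryLow, DTC with mCherryLow, and DTC with mCherryHigh as a test of the difference between the other comparisons), the main test, the settings varied around it, the gene lists and the rule for named genes were chosen before the data were examined. Genes with at least 1 CPM in at least 3 of the 6 libraries of a comparison were tested with limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a mean-variance trend, two-sided, on group alone, and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. Gene lists with at least 5 tested genes were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists, beside an estimated correlation. The number of members called was counted over all genes and adjusted over the list alone. For the comparison with genes of similar level, each member was set against the median of the 200 genes outside the list nearest in mean log2(CPM + 1) over both groups. The 39 lists of pathways and of cell types of pancreas, lung and blood hold 1135 entries, of which 1079 were found, 17 of them through the gene ID. The list of RNA encoded by the mitochondrial genome had 0 of its 15 genes in the table and was not tested. The lists tested numbered 37, 38 and 38 in the 3 comparisons.

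Gstt1 was tested in addition with an exact two-sided permutation test. The named genes are Gstt1, the 10 largest rises and 10 largest falls (5 each for DTC with mCherryHigh) among genes past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the groups, and up to 4 members of each described list with the smallest p, plus a fixed set of marker genes. Predicted genes, ribosomal protein genes and sex-linked genes were passed over in the ranking, and where too few genes passed, places went to genes with an unadjusted p under 0.05, said not to have passed. Genes with at least 90% unique windows in the ribosomal protein list, and members named because they passed adjusted over the list alone, were chosen after their values were seen. A few results are not reported here.

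Alternatives were other pseudocounts and filters, quantile and median-of-ratios scaling, other variance settings, one fit of all 9 libraries, array weights, the label number as a block and leaving out each library. Alternatives chosen after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, thinning to the shallowest depth, genes with unique windows alone, removal of a transcript length trend, the libraries numbered 5 and 6 alone, and the label's code series as a term. Transcript lengths and the share of 50-base windows unique among annotated transcripts came from a GENCODE annotation of a later genome build than mm9, to which 94.0% of gene IDs matched, so no coordinates are given. The overlap of effects was set against 100 simulations of unchanged groups. The whole procedure was tested on simulated data made from the recovered reads with 50 changed genes at each of several fold changes. Of these, limma recovered 1, 22, 30 and 45 of 50 at 2-, 4-, 8- and 16-fold for mCherryHigh with mCherryLow and 1, 5, 36 and 48 of 50 for DTC with mCherryLow.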

Results

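RNA was sequenced from mouse pancreatic ductal adenocarcinoma cells recovered from the lungs of mice that had been injected through the tail vein. The genotype on the labels combines floxed Sirt6 and p53 alleles with the pancreatic driver p48-Cre. The cells carried GFP and a Gstt1-mCherry reporter, where Gstt1 is a glutathione S-transferase that conjugates glutathione to reactive compounds. The 3 groups of 3 libraries each were mCherryLow and mCherryHigh, both sorted 6 weeks after injection, and the cells labelled DTC, sorted by GFP at 5 days. The labels do not say that the libraries of a group came from separate mice, so the spread between them may be technical.

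Library totals recovered from the deposited values were 2051270, 10650000 and 11861200 reads for mCherryLow 1, 5 and 6. They were 643748, 9800170 and 9779100 reads for mCherryHigh 1, 5 and 6, and 1313870, 2052620 and 923988 reads for DTC 1, 2 and 3. Within groups, the Spearman correlation across genes lay between 0.760 and 0.937. The first principal component held 58.6% of the variance and parted DTC from both other groups, and the second held 13.3% and parted mCherryHigh 1. Codes in the label descriptions put all 3 DTC libraries in a series of their own. What the codes mean is not stated. That series, the time after injection and the sort gate cannot be told apart from the DTC state. Among the 6 sorted libraries, mCherryLow 1 and mCherryHigh 1 shared a code series, mCherryLow 5, mCherryLow 6 and mCherryHigh 5 shared another, and mCherryHigh 6 was alone in its own.

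Gstt1 (ENSMUSG00000001663) tracked the sort on its reporter. Its mean was 18.8 ± 9.32 CPM (SD, n = 3) in mCherryLow, 53.3 ± 6.44 CPM (SD, n = 3) in mCherryHigh and 8.29 ± 2.63 CPM (SD, n = 3) in DTC. Every mCherryHigh library lay above every mCherryLow library. The closest pair was mCherryHigh 5 at 48.4 CPM (95% exact Poisson interval 44.1 to 52.9) and mCherryLow 6 at 29.4 CPM (26.4 to 32.7). Such intervals cover counting error only. The difference of mCherryHigh minus mCherryLow was 1.55 (SE 0.42) on the log2(CPM + 1) scale, a 2.92-fold difference. The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 allow, and the limma adjusted p over all genes was 0.444. Within code series, Gstt1 was at 60.6 CPM in mCherryHigh 1 against 15.1 CPM in mCherryLow 1, and at 48.4 CPM in mCherryHigh 5 against 11.9 and 29.4 CPM in mCherryLow 5 and 6. mCherryHigh 6, at 50.9 CPM, had no mCherryLow library in its series.

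In DTC, Gstt1 was lower than in both sorted groups. Against mCherryHigh it fell by 2.58 on the log2(CPM + 1) scale (SE 0.49, limma adjusted p = 0.0042). Against mCherryLow the difference was -1.03 (SE 0.56, limma adjusted p = 0.157), which passed only with quantile normalization, at -2.32 with an adjusted p of 0.0244. The 3 DTC values rest on 8, 23 and 7 reads.

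**Figure D1:**
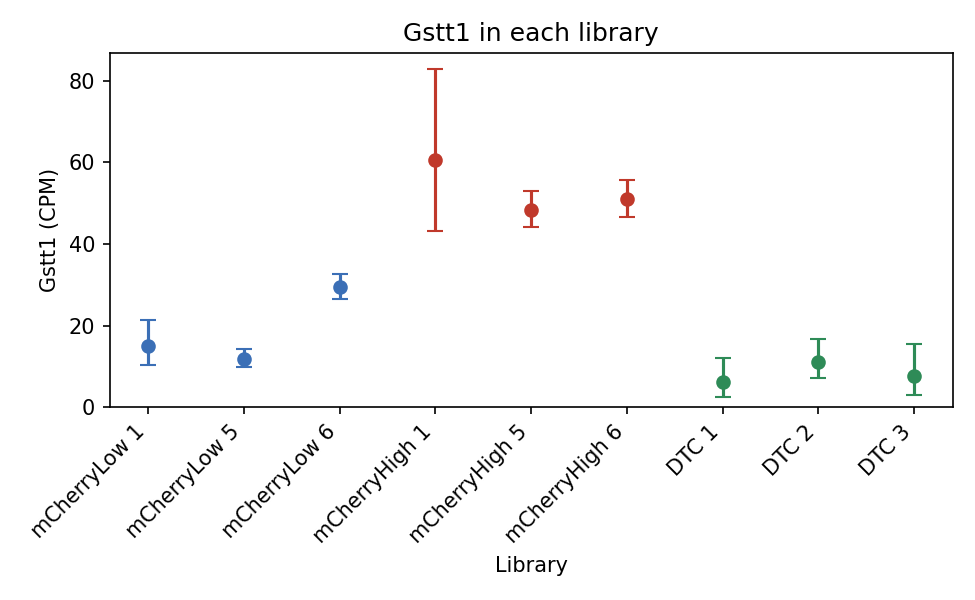
Gstt1 in CPM (vertical axis) in each of the 9 libraries (horizontal axis), with bars for the 95% exact Poisson interval. The mCherryHigh libraries lie between 48.4 and 60.6 CPM, the mCherryLow libraries between 11.9 and 29.4 CPM and the DTC libraries between 6.09 and 11.2 CPM.

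The comparison of mCherryHigh with mCherryLow asks how metastatic tumour cells with a high Gstt1 reporter signal differ from those with a low one. Genes that replicate DNA, MYC targets that build ribosomes, ribosomal proteins and respiratory chain subunits were lower as groups in mCherryHigh. Epithelial genes, such as the transcription factor Elf3 and the tight-junction claudin Cldn4, and matrix genes, such as the collagen chain Col6a1, were higher as groups, and each of these lists lost its call with an estimated correlation (adjusted p = 0.813 with an estimated correlation). Single genes, Gstt1 included, did not pass the test across all genes.

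The replication genes were lower in mCherryHigh, led by Gins2 and Mcm6, both parts of the helicase that opens DNA at replication forks. Gins2 was at 55.2 CPM in mCherryLow and 14.2 CPM in mCherryHigh, a difference of -1.89 on the log2(CPM + 1) scale, which is used for all fold changes given here. Mcm6 was at 242 and 78.2 CPM (-1.62). E2f1, the transcription factor that opens S phase, differed by -1.15, and Rrm2, the ribonucleotide reductase subunit that makes deoxynucleotides, by -1.41. Of the 43 members of the DNA replication and S phase list, 35 were lower, with a median of -0.41 (camera, adjusted p = 3.98e-07). Mitotic genes were lower by less, with a list median of -0.16 over 48 genes (camera, adjusted p = 0.00779). Among them the mitotic cyclin Ccnb2 was at 88.8 CPM in mCherryLow and 12.3 CPM in mCherryHigh, and Ccna2, a cyclin of S phase and mitosis, at 71.1 and 31.5 CPM. Mki67, the common proliferation marker, went the other way, at 109 and 141 CPM (0.42). The replication list had adjusted p = 0.813 with an estimated correlation, and the mitotic list had adjusted p = 0.836 with an estimated correlation.

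Genes for making ribosomes and for respiration were lower in mCherryHigh as well. The MYC target list had a median of -0.36, with 35 of 40 genes lower (camera, adjusted p = 1.08e-06). Its members included Nop16, a nucleolar assembly factor (-1.34), Rrs1, which assembles the large ribosomal subunit (77.0 CPM in mCherryLow and 5.21 CPM in mCherryHigh), and the spermidine synthase Srm (-1.09). Myc itself was at 331 and 225 CPM. Of 71 cytosolic ribosomal protein genes, 57 were lower, with a median of -0.37 (camera, adjusted p = 3.98e-07). The members with the smallest p there, Rpl28, Rpl27 and Rpl11, have near-identical copies in the genome, so their values are uncertain. The oxidative phosphorylation list had a median of -0.26, with 57 of 63 genes lower (camera, adjusted p = 3.20e-06). Ndufa13 and Ndufb8 of respiratory complex I differed by -0.54 and -0.48, and Sdhd of complex II by -0.44. In the unfolded protein and integrated stress response list (32 genes, median -0.23, camera, adjusted p = 0.0144), the mitochondrial folate enzyme Mthfd2 was at 98.0 CPM in mCherryLow and 11.5 CPM in mCherryHigh. Each of these 4 lists had adjusted p = 0.813 with an estimated correlation.

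Epithelial and matrix genes were higher in mCherryHigh. Elf3 was at 28.5 CPM in mCherryLow and 114 CPM in mCherryHigh (2.01), and Cldn4 at 14.6 and 56.03 CPM (2.35). The desmosome protein Dsp differed by 1.44 and Grhl2, a transcription factor that maintains epithelial identity, by 1.81. Smaller values were seen for the adhesion protein Cdh1 (0.61), the ductal keratin Krt19 (0.46) and Epcam (0.47). The epithelial list had a median of 0.60, with 28 of 34 genes higher (camera, adjusted p = 0.000579). In the extracellular matrix and integrin list, 47 of 54 genes were higher, with a median of 0.49 (camera, adjusted p = 0.000562). Col6a1 was at 23.7 and 131 CPM, the basement membrane collagen Col4a5 at 14.6 and 60.4 CPM and Itgb4, the integrin of hemidesmosomes, at 38.5 and 88.8 CPM. The laminin chain Lama4 differed by 1.38 and fibronectin, Fn1, by 0.70. The lung fibroblast and pericyte list, with Cspg4 (1.36) and Rgs5 (1.06), had a median of 0.60 over 15 genes (camera, adjusted p = 0.0288). Of its 19 genes in the table, 8 had a mean of 5 CPM or more in the mCherryLow libraries, and other lists hold 4. These 3 lists each had adjusted p = 0.813 with an estimated correlation.

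The glutathione list did not pass (camera, adjusted p = 0.661), with 21 of its 37 genes higher and 16 lower in mCherryHigh and none past limma. Its members with the smallest p, besides Gstt1, were Ggt1, which cleaves glutathione outside the cell (0.685 CPM in mCherryLow and 9.85 CPM in mCherryHigh), and the transferases Gsta3 (2.06 and 12.5 CPM) and Gstm7 (0.621 and 3.73 CPM). The median of that list was 0.12, and -0.04 with median-of-ratios scaling. The chemokine Cxcl5 was at 87.4 and 316 CPM and Cxcl1 at 77.9 and 259 CPM, neither past the test, and their NF-kB list did not pass (camera, adjusted p = 0.315). Vegfa, the hypoxia-induced angiogenic factor, was at 45.8 and 188 CPM, and Ddit4, an mTOR inhibitor induced by hypoxia, at 10.4 and 55.7 CPM. The hypoxia list had an adjusted p of 0.468 with camera. The macrophage and monocyte list did not pass either (camera, adjusted p = 0.315), with Itgam at 1.76 and 5.10 CPM.

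Among single genes, the largest values higher in mCherryHigh were those of Sall1, a zinc-finger factor of organ development (0.419 CPM in mCherryLow and 26.7 CPM in mCherryHigh), the microtubule-binding protein Mid2 (3.79) and Spin4, a reader of histone methylation (3.76). They were followed by the lipid phosphatase Inppl1 (19.2 and 199.8 CPM), Mst1r, a receptor kinase of epithelial motility (0.947 and 19.6 CPM), the glucosyltransferase Alg10b (3.26), the adenosine receptor Adora2a (4.09 and 46.1 CPM) and Lrrc20 (3.17). Aldh1a3, which makes retinoic acid, was at 15.7 and 92.6 CPM, and the scaffold protein Grasp differed by 2.96. The largest values lower in mCherryHigh were those of Rasa3, a GTPase-activating protein (131 and 1.87 CPM), BC017158 (-4.79), Farsb, a subunit of phenylalanyl-tRNA synthetase (283 and 19.5 CPM), the recombination factor Psmc3ip (-4.21) and the phosphatase subunit Ppp2r5d (-4.02). Bysl, needed for small ribosomal subunits, differed by -3.73, and Chaf1a, which loads histones on new DNA, at 79.0 and 7.45 CPM. Prps1l3 (-3.65), Impa1 (-3.53) and Ctu2 (-3.44) followed. All 3 libraries of one group lay above all 3 of the other for each of these 20 genes, and none passed the limma test. DESeq2 called 8 of the 10 higher ones, all but Mid2 and Aldh1a3, and 6 of the 10 lower ones, all but Rasa3, Bysl, Chaf1a and Impa1.

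Of 15437 genes tested, limma called 0 and edgeR called 0, while DESeq2 called 49 higher and 99 lower. Its calls included Gins2, Mcm6, Ccnb2, Nop16, Rrs1 and Mthfd2 as lower and Elf3, Col6a1, Col4a5, Ggt1 and Ddit4 as higher. At an unadjusted p under 0.05, limma gave 1448 genes (939 higher and 509 lower in mCherryHigh) and edgeR gave 1221. The smallest limma adjusted p was 0.444. Groups did not overlap for 2460 genes (15.9%), where chance gives 10%. In simulated data of this size, limma recovered 22 of 50 genes changed 4-fold and 30 of 50 changed 8-fold. Over all genes, 0 members of any list were called up and 0 down. Adjusted over the list alone, 0 were up and 2 down in the replication list (Gins2 and Mcm6), 1 up and 0 down in the epithelial list (Elf3) and in the hypoxia list (Vegfa), and 0 up and 1 down in the alveolar type 1 list (Cav1). The other lists had 0 up and 0 down adjusted over the list alone. Of 37 lists, 9 were called with camera's preset correlation, and all of them were lost with an estimated correlation.

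With the code series as a term in the model, Gstt1 differed by 1.58, and 7 of the 9 list calls remained. Those of the mitotic list (adjusted p = 0.354) and the stress response list (adjusted p = 0.196) did not. Quantile normalization ended the calls of the mitotic (adjusted p = 0.0790), stress response (0.275) and fibroblast and pericyte (0.0790) lists. Some list calls rested on single libraries. The mitotic list had an adjusted p of 0.766 without mCherryLow 5 and 0.581 without mCherryHigh 6. The stress response list lost its call without mCherryLow 5 (0.124), mCherryLow 6 (0.0848), mCherryHigh 1 (0.123) or mCherryHigh 6 (0.0928). The fibroblast and pericyte list lost its call without mCherryLow 1 (0.186), mCherryLow 5 (0.0965), mCherryHigh 5 (0.159) or mCherryHigh 6 (0.0629). With every library thinned to the depth of the shallowest, the replication list (adjusted p = 0.00324) and the MYC target list (adjusted p = 0.0459) kept their calls and the other 7 lost them.

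**Figure D2:**
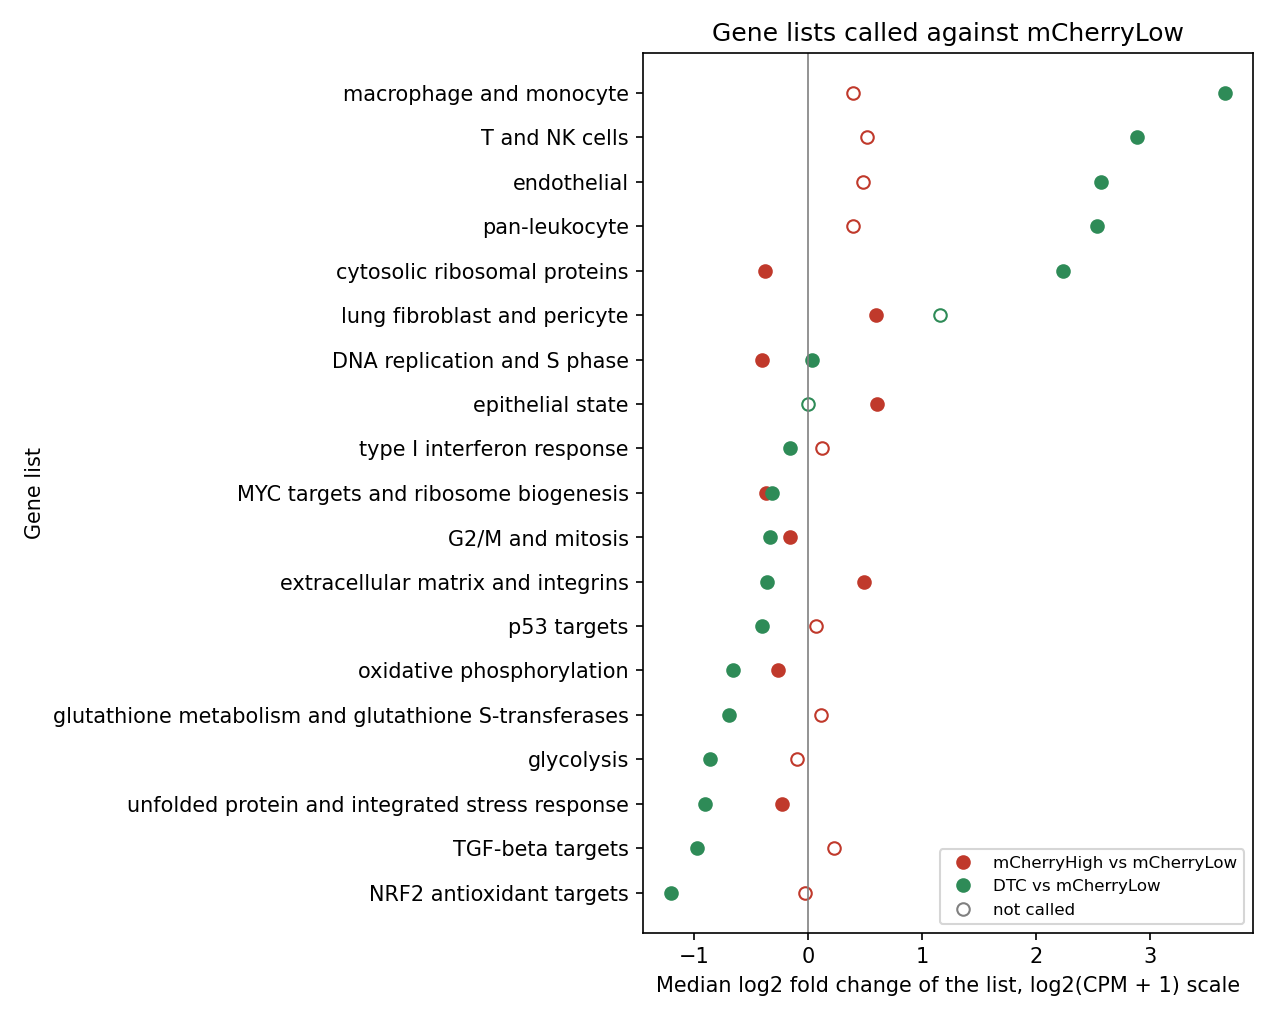
Median log2 fold change on the log2(CPM + 1) scale (horizontal axis) of each gene list called in at least 1 comparison with mCherryLow (vertical axis), for mCherryHigh in red and DTC in green, filled where the list was called, with 1 called list not shown. As measured, the ribosomal protein list lies at -0.37 for mCherryHigh and 2.24 for DTC, and the macrophage list at 3.66 for DTC.

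The comparison of DTC with mCherryLow asks how tumour cells recovered 5 days after injection differ from cells of established metastases with a low reporter signal. Genes of macrophages, of other leukocytes, of endothelium and of cytosolic ribosomal proteins rose as groups, led by Chi3l3, a chitinase-like protein of macrophages, and by MHC class II genes. Antioxidant genes under NRF2, targets of TGF-beta and genes of protein folding in the endoplasmic reticulum fell as groups, and each of these lists lost its call with an estimated correlation (adjusted p = 0.116 to 0.583 with an estimated correlation). The chromatin gene Hmga2 rose, while the tight-junction gene Cldn4 and the surface antigen Psca fell.

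Of 18701 genes tested, limma called 6405 higher and 1659 lower in DTC, so that 79.4% of calls were higher. The median of all genes was shifted by 0.59. The shift was 0.28 with median-of-ratios scaling and -0.07 with quantile normalization, where 2608 genes were higher and 1856 lower (58.4% higher). edgeR called 4558 higher and 3095 lower. Of the genes called higher by limma, 5199 (81.2%) had a mean under 5 CPM in mCherryLow, and 673 were pseudogenes. Of 1023 pseudogenes tested, 673 were called higher and 9 lower, against 4497 higher and 1623 lower of 15682 protein-coding genes. The groups did not overlap for 9952 genes (53.2%), where chance gives 10%. Olfactory receptor genes, silent in most tissues, had means of 4.24 to 10.8 CPM in the DTC libraries. List medians are therefore given relative to the shift of 0.59, while single genes are given as measured. Since the rises lay mostly among weakly expressed genes, lists were also set against genes of similar level, a comparison chosen after the results were seen, in which 12 of the 13 lists called lower and all 5 called higher kept their direction. Direction was counted at any size. Among those called lower, the medians of the replication, oxidative phosphorylation, mitotic and glycolysis lists were near 0, at -0.0025, -0.03, -0.09 and -0.13. Without DTC 1 or DTC 3 the genes called numbered 3628 and 4387.

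The macrophage and monocyte list had a median 3.07 above that of all genes (30 genes, camera, adjusted p = 1.09e-05), with 22 members up and 0 down over all genes, and 23 up and 0 down adjusted over the list alone. Chi3l3 (ENSMUSG00000040809) was at 0.488 CPM in mCherryLow and 1516 CPM in DTC (limma adjusted p = 4.12e-06). Only 70.6% of its 50-base windows are unique, so reads of close relatives may be included. Lysozyme, Lyz2, was at 105 and 2454 CPM. The MHC class II genes H2-Ab1, H2-Aa and H2-Eb1 went from 2.96, 1.33 and 1.49 CPM to 301, 225 and 202 CPM. The lysosomal protease Ctss, which trims antigens, was at 20.1 and 807 CPM, and the complement component C1qa at 0.194 and 82.4 CPM. Of the 30 genes, 18 had a mean of 5 CPM or more in the mCherryLow libraries, and which cells gave those reads was not tested. The list had adjusted p = 0.508 with an estimated correlation.

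Lists of endothelium, of T and NK cells and of leukocytes in general rose too, by medians of 1.42, 0.83 and 1.61 above genes of similar level. The endothelial list had a median 1.98 above that of all genes (21 genes, camera, adjusted p = 0.000165), with 17 members up and 0 down over all genes and 19 up and 1 down adjusted over the list alone. The endothelin receptor Ednrb was at 0.325 CPM in mCherryLow and 49.6 CPM in DTC, Tmem100 at 0.391 and 52.3 CPM, the clotting protein Vwf at 7.04 and 94.7 CPM, and the receptor partner Ramp2 at 1.13 and 31.2 CPM. The list had adjusted p = 0.508 with an estimated correlation. The T and NK cell list (17 genes, camera, adjusted p = 0.0057) had a median 2.30 above that of all genes, with 12 up and 0 down over all genes and 14 up and 0 down adjusted over the list alone. The coreceptor Cd4 was at 16.1 CPM in DTC, Il7r, a cytokine receptor of lymphocytes, at 35.8 CPM and the T cell receptor subunit Cd3g at 23.7 CPM. The call was lost with quantile normalization (adjusted p = 0.0550), and the list had adjusted p = 0.583 with an estimated correlation. The pan-leukocyte list (25 genes, camera, adjusted p = 0.0205) had a median 1.94 above that of all genes, with 14 up and 1 down over all genes and 17 up and 1 down adjusted over the list alone. Its members Cytip, Cd84, Ikzf1 and Dock2, which act in leukocyte adhesion, signalling, lineage choice and migration, were at 145, 104, 70.9 and 92.1 CPM in DTC against 8.89, 8.12, 5.32 and 11.9 CPM. That list had adjusted p = 0.583 with an estimated correlation, and array weights ended its call (adjusted p = 0.0730).

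In mCherryLow, 4 of 21 endothelial genes, 2 of 21 T and NK cell genes and 19 of 25 pan-leukocyte genes had a mean of 5 CPM or more. Other lists hold 0, 2 and 0 of the genes of these lists. The alveolar type 2 list did not pass (13 genes, camera, adjusted p = 0.435), although 6 members were up and 0 down over all genes and 7 up and 0 down adjusted over the list alone. The surfactant gene Sftpa1 was at 2.07 CPM in mCherryLow and 65.7 CPM in DTC, and Sftpc at 0.353 and 64.3 CPM with an SD of 96.2 over the 3 DTC libraries and no call with quantile normalization (adjusted p = 0.0970). Among the largest rises outside the lists were BC018473 (149 CPM in DTC), the mitochondrial leucyl-tRNA synthetase Lars2 (427 and 31469.5 CPM), Stox2 (81.5 CPM) and the carbonic anhydrase Car4 (85.6 CPM). Together with Gm10800 and Gm10801, Lars2 held 11.8%, 3.47% and 15.1% of DTC 1, 2 and 3. Whether its reads reflect expression of the enzyme was not tested, so its value is uncertain.

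Ribosomal protein genes rose in DTC, with a list median 1.65 above that of all genes (75 genes, camera, adjusted p = 7.1e-10), 62 up and 0 down over all genes and 63 up and 0 down adjusted over the list alone. The smallest p belonged to Rpl19, Rps23, Rpl17 and Rps29, all with near-identical copies, so their values are uncertain. Rpl19, with 20.7% of windows unique, was at 2.14 and 222 CPM. Of the 8 genes with at least 90% unique windows, Rpl24, Rps20, Rps15a and Rpl34 rose, while Rps3 (-0.26) and Rpl8 (0.18) were near 0. The list had adjusted p = 0.578 with an estimated correlation.

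Antioxidant genes fell in DTC. The NRF2 target list had a median 1.79 below that of all genes (25 genes, camera, adjusted p = 3.83e-07), with 1 up and 11 down over all genes and 1 up and 16 down adjusted over the list alone. G6pdx, which opens the pentose phosphate pathway and yields NADPH, was at 214 CPM in mCherryLow and 37.5 CPM in DTC (limma adjusted p = 0.000712). Heme oxygenase, Hmox1, was at 204 and 38.0 CPM, the pentose phosphate enzyme Taldo1 at 708 and 208 CPM and the biliverdin reductase Blvrb at 92.8 and 19.4 CPM. The glutathione list (35 genes, camera, adjusted p = 9.82e-05) had a median 1.28 below that of all genes, with 2 up and 5 down over all genes and 1 up and 3 down adjusted over the list alone. Hagh of the glyoxalase pathway fell by 1.74, the glutaredoxin Glrx by 1.76 and the transferase Gstt3 by 1.85, while the peroxidase Gpx7 rose by 2.54, a call lost with quantile normalization (adjusted p = 0.124). The calls of Glrx and Gstt3 were lost without DTC 1 (adjusted p = 0.0550 and 0.0928), that of Glrx also without mCherryLow 6 (0.0572) and that of Gstt3 also without mCherryLow 1 (0.0663). The NRF2 list had adjusted p = 0.116 with an estimated correlation, and the glutathione list had adjusted p = 0.508 with an estimated correlation. Relative to genes of similar level, their medians were 0.64 and 0.91 lower.

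TGF-beta targets and protein folding genes fell as well. The TGF-beta list (29 genes, camera, adjusted p = 2.74e-06) had a median 1.57 below that of all genes, with 0 up and 10 down over all genes and also adjusted over the list alone. Ltbp3, which stores latent TGF-beta in the matrix, was at 113 CPM in mCherryLow and 30.6 CPM in DTC, the transcription factor Junb at 769 and 322 CPM, and Id3, an inhibitor of differentiation, at 64.0 and 22.8 CPM. In the stress response list (32 genes, camera, adjusted p = 9.11e-07), 0 members were up and 12 down over all genes and 0 up and 11 down adjusted over the list alone, with a median 1.49 below that of all genes. Xbp1, the transcription factor of the unfolded protein response, was at 366 and 117 CPM, the chaperone Calr at 1516 and 470.0 CPM and the disulfide isomerase Pdia4 at 715 and 168 CPM. Slc3a2, a chain of amino acid transporters, fell by 1.32. Without DTC 1, Id3 had an adjusted p of 0.0564 and Pdia4 of 0.0543, and without mCherryLow 6, Id3 had 0.0638. Junb (adjusted p = 0.118) and Slc3a2 (adjusted p = 0.0615) lost their calls with quantile normalization. The TGF-beta list had adjusted p = 0.116 with an estimated correlation, and the stress response list had adjusted p = 0.508 with an estimated correlation. Relative to genes of similar level, their medians were 0.50 and 0.36 lower.

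**Figure D3:**
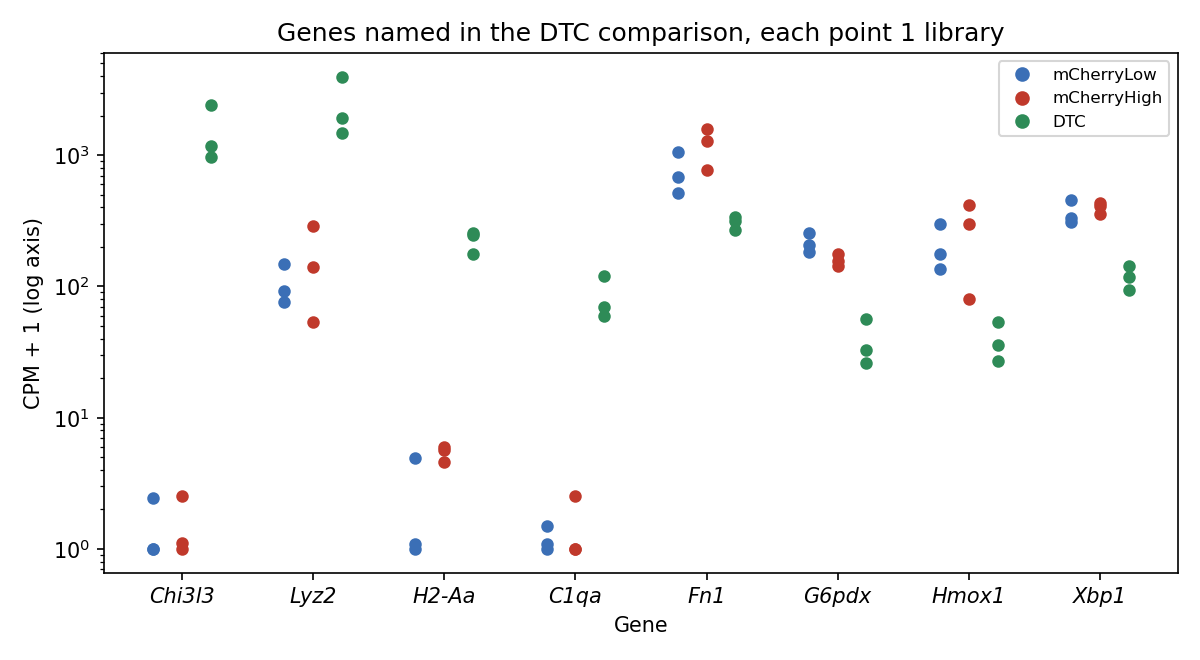
Expression in CPM + 1 on a log axis (vertical) of 8 genes (horizontal axis), each point 1 library, in blue for mCherryLow, red for mCherryHigh and green for DTC. Chi3l3, Lyz2, H2-Aa and C1qa lie higher in all 3 DTC libraries than in the other 6, and Fn1, G6pdx, Hmox1 and Xbp1 lie lower.

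Energy metabolism moved in both directions. The oxidative phosphorylation list (63 genes, camera, adjusted p = 2.16e-06) had 6 up and 22 down over all genes and 6 up and 23 down adjusted over the list alone. The complex II subunit Sdha was at 441 CPM in mCherryLow and 109 CPM in DTC, while cytochrome c, Cycs, was at 7.35 and 83.3 CPM and Cox7c of complex IV at 4.96 and 79.7 CPM. In the glycolysis list (23 genes, camera, adjusted p = 0.017), 4 were up and 8 down over all genes and also adjusted over the list alone. The phosphofructokinase Pfkl fell by 1.96 and the glucose transporter Slc2a3 rose by 4.44. Gapdh was at 13.8 and 412 CPM and Pgk1 at 12.5 and 82.7 CPM, both uncertain because of near-identical copies. Quantile normalization ended both list calls (adjusted p = 0.314 and 0.413), and the glycolysis call was lost without DTC 1 (0.0785), DTC 2 (0.0532) or DTC 3 (0.224). The oxidative phosphorylation list had adjusted p = 0.563 with an estimated correlation, and the glycolysis list had adjusted p = 0.508 with an estimated correlation. Relative to genes of similar level, their medians were only 0.03 and 0.13 lower.

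Matrix, epithelial and mesenchymal genes also split. Fn1 was at 751 CPM in mCherryLow and 305 CPM in DTC (-1.24), a call lost with quantile normalization (adjusted p = 0.227), without mCherryLow 1 (0.0944) and without DTC 1 (0.0871). The integrin chain Itgb5 fell by 2.49 and Itgb6, its epithelial relative, rose by 4.04. The proteoglycan Vcan rose to 231 CPM and the collagen chain Col1a2 to 51.9 CPM. The matrix list (55 genes, camera, adjusted p = 0.0028) had 7 up and 11 down over all genes and also adjusted over the list alone, and lost its call with quantile normalization (adjusted p = 0.0806) and without DTC 3 (0.224). It had adjusted p = 0.563 with an estimated correlation, and a median 0.15 below genes of similar level. Cldn4 went from 14.6 to 0.254 CPM and the desmosome gene Perp from 165 to 26.8 CPM, whereas Marveld3 of tight junctions and the splicing factor Esrp1 rose by 2.80 and 2.85, both lost with quantile normalization (adjusted p = 0.211 and 0.256). Krt19 differed by -1.59 (limma adjusted p = 0.0976), and passed with median-of-ratios scaling (adjusted p = 0.0367) and without DTC 2 (0.0334). The epithelial list did not pass (36 genes, camera, adjusted p = 0.136; 6 up and 3 down over all genes, 5 up and 3 down adjusted over the list alone), and its median was 0.59 below that of all genes, with a test pointing down, while as measured its median was 0.00 and its mean 0.15.

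The mesenchymal list did not pass (34 genes, camera, adjusted p = 0.0565), with 6 up and 6 down over all genes and also adjusted over the list alone, and a median 0.80 below that of all genes (as measured, a median of -0.21 and a mean of 0.13, under a test pointing down). The receptor kinase Axl was at 730.2 CPM in mCherryLow and 153 CPM in DTC, the fibronectin receptor chain Itga5 at 276 and 65.5 CPM, the cytoskeletal linker Msn fell by 1.81 and the transcription factor Prrx1 rose by 3.90. Vim differed by -0.34 and by 0.14 with quantile normalization. The oncofetal list did not pass (13 genes, camera, adjusted p = 0.399), although 6 members were up and 0 down over all genes and also adjusted over the list alone. Hmga2, a chromatin protein of embryonic growth, went from 16.2 to 157 CPM and Lin28b, which blocks let-7 microRNAs, from 3.78 to 26.6 CPM. The Notch ligand relative Dlk1 rose by 3.39 and the RNA-binding protein Igf2bp3 by 2.66. Quantile normalization ended the calls of Lin28b (adjusted p = 0.226), Dlk1 (0.0686) and Igf2bp3 (0.175), and Lin28b also lost its call without DTC 1 (0.0589) and without DTC 3 (0.0528). Sirt6 differed by -0.58 (limma adjusted p = 0.441), and by -1.97 with quantile normalization (adjusted p = 0.0356).

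The mitotic list (48 genes, camera, adjusted p = 0.000251) had 1 up and 3 down over all genes and 1 up and 0 down adjusted over the list alone. The mitotic kinases Plk1 and Ttk and the kinesin Kif20a fell by 2.21, 2.13 and 2.59, while Cks2, a partner of cyclin-dependent kinases, rose by 2.84. Mki67 differed by -0.05 and by 0.22 with quantile normalization. The list call was lost with quantile normalization (adjusted p = 0.134) and without DTC 3 (0.180). Without DTC 1, the calls of Plk1 (adjusted p = 0.0868), Ttk (0.197) and Kif20a (0.0984) were lost, and leaving out mCherryLow 5 also ended all 3 of them (0.0546, 0.141 and 0.112). Plk1 and Kif20a lost their calls without DTC 3 (0.0891 and 0.126), Plk1 and Ttk without mCherryLow 1 (0.0714 and 0.0580) and Ttk without mCherryLow 6 (0.0671). Quantile normalization ended the calls of Kif20a (0.0567) and Cks2 (0.0530). The list had adjusted p = 0.583 with an estimated correlation, and a median 0.09 below genes of similar level. Further large falls were those of the protease Mmp10 (62.9 and 1.86 CPM), the kallikrein Klk8 (-3.67), Serinc2 (-3.63), Psca (24.9 and 1.34 CPM), the carbonic anhydrase Car2 (53.9 and 4.05 CPM), the galectin ligand Lgals3bp (747 and 141 CPM) and the glucosamine enzyme Gnpda1 (-3.16). Mir5115 and Mir5105, short microRNA genes whose reads can come from other transcripts, fell by 4.36 and 3.44. Quantile normalization ended the call of Lgals3bp (adjusted p = 0.0571). Thinning every library to the shallowest depth ended the calls of 36 named genes, and that of Gstt3, which was then at 0.11. Of 38 lists, 18 were called with the preset correlation and 0 with an estimated correlation.

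**Figure D4:**
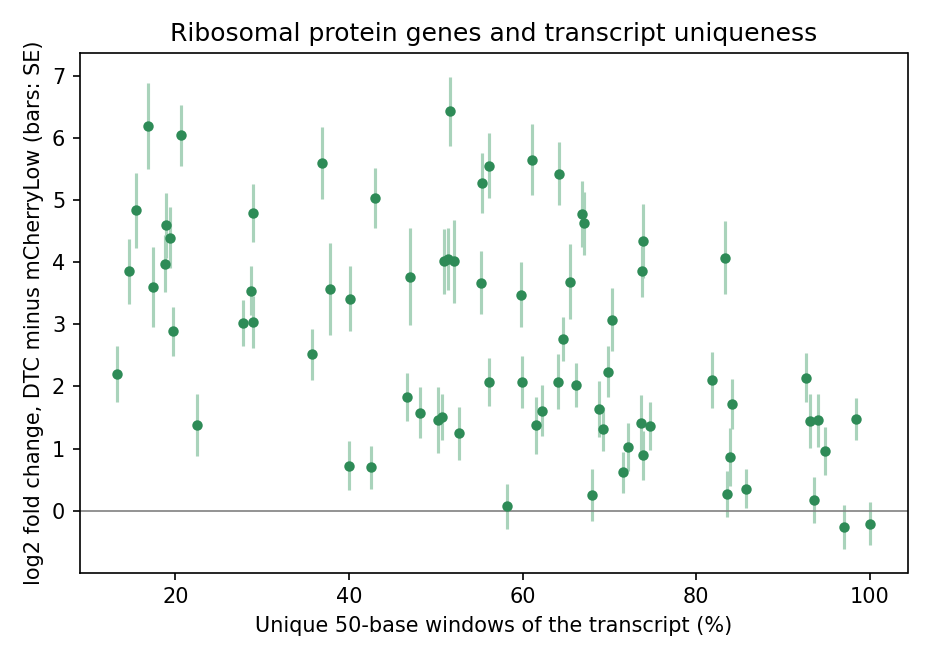
Log2 fold change of DTC minus mCherryLow on the log2(CPM + 1) scale (vertical axis, bars for the SE) against the percentage of unique 50-base windows of the transcript (horizontal axis) for ribosomal protein genes, each point 1 gene. Genes with fewer unique windows lie higher (Spearman rho -0.50 across genes, which are not independent replicates).

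The comparison of DTC with mCherryHigh tests directly whether the DTC and mCherryHigh effects differ. Among the largest rises in DTC were the macrophage gene Chi3l3, the complement component C1qb, the MHC class II gene H2-Eb1, the lectin Clec4n and the mast cell receptor Mrgprb1. The claudin Cldn4, the protease Mmp10, the basal keratin Krt17 and the synaptic vesicle gene Syn1 were among the largest falls. Gstt1 fell as well.

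Limma called 4532 genes higher and 1417 lower of 19700 tested, with a shift of the median of all genes of 0.55, and edgeR called 3091 higher and 2198 lower. With quantile normalization 1738 were higher and 1237 lower, with a shift of 0.05, and with median-of-ratios scaling 4029 and 1914, with a shift of 0.39. Groups did not overlap for 8800 genes (44.7%), where chance gives 10%. Chi3l3 rose by 9.95, Clec4n by 6.11 and Mrgprb1 by 5.93, and C1qb was listed at 0 in all 3 mCherryHigh libraries and at 78.8 CPM in DTC. Cldn4 went from 56.03 CPM in mCherryHigh to 0.254 CPM in DTC, Mmp10 from 112 to 1.86 CPM, Krt17 from 107 to 12.0 CPM and Syn1 from 114 to 6.57 CPM. Mir5115 fell by 6.02, with the same limit as above, and the Krt17 call was lost with DESeq2 (adjusted p = 0.133). Thinning ended the calls of Cldn4 (adjusted p = 0.169), Krt17 (0.0552) and Syn1 (0.0650). Of 38 lists, 20 were called, 5 up and 15 down. The ribosomal protein list was 2.23 above the median of all genes (66 up and 0 down over all genes, 69 up and 0 down adjusted over the list alone, camera, adjusted p = 5.21e-17, adjusted p = 0.384 with an estimated correlation). The matrix list was 1.56 below it (5 up and 16 down over all genes, 5 up and 18 down adjusted over the list alone, camera, adjusted p = 1.10e-06, adjusted p = 0.215 with an estimated correlation). The epithelial list was 1.03 below it (4 up and 7 down over all genes, 3 up and 6 down adjusted over the list alone, camera, adjusted p = 0.00131, adjusted p = 0.215 with an estimated correlation). Relative to genes of similar level, the medians of these 3 lists were at 2.84, -0.95 and -1.09. With an estimated correlation 0 lists were called. Without mCherryHigh 5, mCherryHigh 6, DTC 1 or DTC 3 the genes called numbered 3588, 3911, 2538 and 3265.

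Across 15143 genes, the DTC and mCherryHigh effects against mCherryLow had a Pearson r of 0.34 and a Spearman rho of 0.36. Both effects share the mCherryLow libraries, and 100 simulations of unchanged groups with that sharing gave a mean r of 0.43. The simulated groups had no effects of their own, and r depends on the size of the effects, so these r values are not a like comparison. The covariance was 0.405 against a simulated mean of 0.183 and a highest simulated value of 0.202. Each gene was drawn independently in the simulation, which leaves out variation shared across genes, so the covariance does not decide on a common change. Effects had the same sign for 64.2% of genes, against 64.3% in simulation. At an unadjusted p under 0.05, 459 genes were higher in both (242 if independent) and 165 were lower in both (80.5 if independent). With adjusted calls the overlap was 0, since limma called 0 genes in mCherryHigh. Genes are not independent replicates, and shared mCherryLow libraries can by themselves give an excess over independence. The size of that excess was not simulated, so these counts alone do not show a change common to DTC and mCherryHigh.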

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

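The tests with edgeR and DESeq2, thinning, unique windows, the length trend, the libraries numbered 5 and 6 and the code series were chosen only after the results were seen, and the other alternatives were planned. For mCherryHigh with mCherryLow, limma called 0 genes under each limma alternative and each omitted library, and edgeR called 0, with 1221 at an unadjusted p under 0.05. DESeq2 called 148 genes. The number of lists called was 6 with quantile normalization, which ended 3 of the 9 calls, 2 after thinning, 0 with an estimated correlation and 6 to 11 when libraries were left out in turn. Gstt1 lay between 1.29 and 1.90 in the same omissions. With the label number as a block, limma called 0 genes (1342 unadjusted), edgeR called 0 (1115 unadjusted) and 9 lists were called, with Gstt1 at 1.55. Titles of same-number libraries share a letter as well as the number, but the labels do not say that a number marks a mouse. The main fit therefore had no block, a choice made beforehand. Same-number libraries had correlations of -0.20, -0.02 and 0.27, which are too few to exclude pairing.

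For DTC with mCherryLow, the genes called numbered 4464 with quantile normalization, 4779 among genes with unique windows, 3070 after thinning and 3628 to 7008 when libraries were left out. The count among unique windows was lower partly because fewer genes were tested. Lists called numbered 8 with quantile normalization, 0 with an estimated correlation and 10 to 20 when libraries were left out, with 10 without DTC 3. Gstt1 was at -2.32 with quantile normalization, where it passed. For DTC with mCherryHigh, genes called numbered 2975 with quantile normalization, 9545 with array weights, 3418 with unique windows, 1309 after thinning and 2538 to 6997 when libraries were left out. Lists called numbered 10 with quantile normalization, 0 with an estimated correlation and 13 to 21 when libraries were left out, with 13 without DTC 3. Apart from the smaller gene set, the cause of these changes was not tested.

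Directions reversed for a few values that had not passed. In mCherryHigh these were Krt19 with numbers 5 and 6 alone (-0.0121), Cdh1 after thinning (-0.00386) and Manf after thinning (0.0647). In DTC with mCherryLow these were Mki67 (0.22 with quantile normalization, 0.15 with array weights, 0.20 after thinning and -0.27 to 0.21 when libraries were left out, above 0 without mCherryLow 5 and without DTC 3) and Vim (0.14 with quantile normalization). Gstt3, which had passed, was at 0.11 after thinning, and the MYC target list had adjusted p from 0.00106 to 0.745 when libraries were left out, turning up without DTC 3. The cause was not tested. Among the other values of named genes for mCherryHigh with mCherryLow, 1727 kept their direction and stayed uncalled, since the main fit had called 0 genes. Another 27 newly passed, all with DESeq2. For DTC with mCherryLow, 1644 kept direction and outcome, whether passed or not, 90 lost the call and 3 newly passed. For DTC with mCherryHigh, 185 kept both and 4 lost the call. Among lists, 169, 290 and 338 values kept both and 37, 68 and 61 lost the call in the 3 comparisons. The correlation of the DTC and mCherryHigh effects ran from 0.23 to 0.37 across settings and from 0.27 to 0.42 when libraries were left out. Depth limited mCherryHigh 1 most, where 1 read is 1.55 CPM, against 0.487 to 1.08 CPM in mCherryLow 1 and the DTC libraries and 0.0843 to 0.102 CPM in the other 4.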

Other observations

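The tests of macrophages among the sorted cells, of all markers and of the macrophage list per kilobase, of the libraries numbered 5 and 6 alone and of lists against genes of similar level, and the ribosomal protein median relative to all genes, were chosen only after the results were seen. A small set of transcripts took a large part of the DTC libraries. Gm10800, Gm10801 and Lars2 together held 11.8%, 3.47% and 15.1% of DTC 1, 2 and 3, against 0.127% to 0.585% in the other 6 libraries. The 428 olfactory receptor genes, silent in most tissues, had a mean of 7.70, 4.24 and 10.8 CPM in DTC and 0.131 to 2.99 CPM elsewhere. Ribosomal protein genes held 1.86%, 1.31% and 0.985% of DTC reads and 0.333% to 0.539% elsewhere.

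Further lists were called lower in DTC than in mCherryLow with the preset correlation. They were the type I interferon list (adjusted p = 0.0103, with Stat2 at -1.41; adjusted p = 0.583 with an estimated correlation), the p53 target list (adjusted p = 0.0232, with Zmat3 at 3.10; adjusted p = 0.508 with an estimated correlation) and the MYC target list (adjusted p = 0.0205; adjusted p = 0.666 with an estimated correlation). The replication list had a median 0.55 below that of all genes (as measured, a median of 0.04 and a mean of -0.12, under a test pointing down; adjusted p = 0.0259; adjusted p = 0.648 with an estimated correlation). The interferon, p53, MYC and replication lists had 1, 5, 4 and 2 members up and 2, 3, 0 and 1 down over all genes. Adjusted over the list alone, they had 0, 4, 0 and 0 up and 0, 1, 0 and 0 down. Relative to genes of similar level, their medians were at -0.16, -0.26, 0.18 and 0.00, so the MYC list lay higher. All 4 calls were lost with quantile normalization, and also without DTC 3, with adjusted p from 0.0797 to 0.816 in the latter. Lists of B cells (adjusted p = 0.0671), neutrophils (0.0671), airway cells (0.156), alveolar type 1 cells (0.435), mesothelium (0.911) and acinar cells (0.0694) did not pass with camera in DTC. In the sorted cells, the endothelial list (0.0847) did not pass, and the alveolar type 1 list (0.95) had a median of 0.10 under a test pointing down.

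The first pattern is the shift of 9 gene lists between mCherryHigh and mCherryLow. After removal of a trend on transcript length, 7 of the 9 lists kept their call, and without the shallow mCherryHigh 1, 8 kept it, which argues against either as the whole cause. With every library thinned to the shallowest depth only 2 kept it, which met the reading fixed beforehand for a difference in depth as the cause. All 9 medians kept their sign after thinning, with a median size of 0.28 against 0.37, but the mitotic median went from -0.16 to -0.01 and the fibroblast one from 0.60 to 1.09, and thinning removes most reads of both groups. In the libraries numbered 5 and 6, whose depths differ by a factor of 1.21 against 18.4 over all 6, 8 lists kept their call, so these tests conflict on depth, and a difference between the reporter states stays open and untested.

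The second pattern is the rise in DTC of genes with near-identical copies. Genes with few unique windows had a median fold change 0.796 above that of genes with all windows unique (1.14 over 579 genes against 0.35 over 11912), between the bounds set for reads shared among copies and against them. Ribosomal protein genes with at least 90% unique windows had a median of 1.20 as measured, which met the reading fixed beforehand for higher expression of the family, but it was 0.61 relative to all genes, between the bounds, and Rps3 and Rpl8 did not pass the test. Across the family, the fold change went down with the unique share in DTC (Spearman rho -0.50) and not in mCherryHigh (0.14). Both sources may contribute, and these tests do not part them.

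The third pattern is the rise in DTC of markers from 10 lists of leukocytes and lung cells, of which the macrophage, pan-leukocyte, T and NK cell and endothelial lists alone passed camera. The median rise of the 104 called markers was 7.72 times that of olfactory receptor genes, which decides nothing since called markers rise by selection, and over all 184 markers with a transcript length the rise per kilobase was 6.77 CPM against 2.18, a ratio of 3.10 between the bounds for and against reads from unexpressed DNA. The whole macrophage list, called or not (30 genes), rose by 25.4 CPM per kilobase, 11.6 times the olfactory rise (6.48, 14.7 and 14.3 times in DTC 1, 2 and 3). That is past the bound against reads from unexpressed DNA as the source of that list. However, the bound for this list was set after the results were seen, and its ratio was the largest of the 10 lists. For the other markers such reads stay open. Among the other lists the ratio ran from 0.69 for lung fibroblasts and pericytes to 5.82 for the pan-leukocyte list (4.70, 6.85 and 7.67 in DTC 1, 2 and 3). Macrophages among the sorted cells are a candidate source of the macrophage rise. Of the measured macrophage genes, 73.3% (22 of 30) lay above every mCherryLow library. Over all tested genes, the groups did not overlap, in either direction, for 53.2%. The macrophage share lay between its bounds, however, and the GFP gate would remove macrophages that had taken up no GFP. Mrc1, a member of the list, was near equal at 205 CPM in mCherryLow and 213 CPM in DTC. The pan-leukocyte list had means of 25.6 to 41.6 CPM in the mCherryLow libraries. Leukocyte RNA in those libraries was not tested, so Mrc1 decides nothing about macrophages in DTC. Expression of the macrophage genes by the tumour cells themselves at 5 days was not tested.

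Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split of mCherryHigh and mCherryLow called 0 genes and the highest other split called 1, so all 10 splits called as many as the real one. The real splits called 8064 genes for DTC with mCherryLow and 5949 for DTC with mCherryHigh, and the highest other split called 0 in both, so that 1 split, the real one, reached the count.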
